A study of Mus musculus with 2 samples.

How the data were processed

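The series holds 2 circular chromosome conformation capture sequencing (4C-seq) libraries from mouse, both made with a viewpoint at the promoter of Fos. 4C-seq cross-links chromatin, cuts and re-ligates it, and sequences by inverse PCR the DNA that was ligated to 1 chosen site, so that the signal at a position reflects how often it was near that site. Fos is an immediate-early gene that neurons switch on within minutes of stimulation and that encodes a subunit of the AP-1 transcription factor. One library came from cortical neurons of embryonic day 15.5 kept in culture for 10 to 11 days, and the other from hippocampal tissue of mice aged 3 months. Per the labels' protocols, chromatin was fixed with 1% formaldehyde, the fixative was quenched with 0.125 M glycine, the first restriction enzyme is named as HindII and the second as DpnII, ligation lasted 4 hours at 16 °C, and about 16 PCR reactions were combined for a viewpoint. Each group has 1 library, so no difference between the groups has a replicate check and no p-value is given.

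The authors deposited, for each library, a table of contact signal at positions 1 kb apart, in mm9 coordinates per the submitters' processing notes. The aligner, the counting step and the program that made the tables are not given in the sources used here. The cortical table has 2001 positions from 85814834 to 87814834, and the hippocampus table has 201 positions from 86714199 to 86914199. At each position the deposited signal is given for 48 window sizes, with 3 values each: a central signal, an upper bound and a lower bound. The window sizes are not written in the files. The number of windows missing at the region ends follows, at every position checked, windows from 2 to 49 kb in steps of 1 kb, and that reading was used. The central value, after a constant is added (0.00569 in the cortical file and 0.00559 in the hippocampus file), is the geometric mean of the other 2 values, to within 1.25e-14 in the constant. The deposited signal is therefore a mean of logs, turned back to a linear scale, and the bounds are that mean plus and minus a spread. The spread did not shrink as windows widened: its median was 2.05 on the log2 scale in 5 kb windows and 2.21 in 40 kb windows of the cortical file, and 2.80 and 3.06 in the hippocampus file. It was therefore read as the spread of values inside a window, not as the error of the mean. The authors scaled each library so that its highest 2 kb window equals 1, as seen in both deposited tables. Levels in the 2 libraries are thus relative to each library's own maximum. Depth is unknown: the tables give no read counts and no number of fragment ends per window, so no counting interval or detection floor could be given.

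Windows listed at 0 had both bounds at 0 too (64 of 1999 windows of 2 kb in the cortical file and 8 of 199 in the hippocampus file). The 10 kb windows around those positions had a median signal of 0.0944 against 0.115 elsewhere in the cortical file and 0.202 against 0.252 in the hippocampus file. Whether a window at 0 held zeros or no values was tested by comparing each 10 kb window with the 8 kb window inside it that leaves out its outermost 2 kb. Where that 2 kb window was at 0 and stood in a run of 5 or more, the 2 values were equal, to within 1e-12, for 7 of 13 cortical and 4 of 6 hippocampus windows, as for windows without values. In such runs the wider value was higher in 9 and lower in 3 of 26 cortical comparisons, and higher in 4 of 12 hippocampus comparisons. For the other 51 cortical windows at 0 they were never equal, and the wider value was lower in 87 of 102 comparisons and higher in 15. For the other 2 hippocampus windows it was higher in 3 of 3. Lower values would follow from measured zeros. Higher ones cannot come from zeros alone, nor from windows without values, so the inferred window limits may not be exact to the fragment. For windows with unequal values the test did not settle the matter. Start and end coordinates of windows given below follow the inferred sizes. Windows at 0 were left out, and kept in an alternative with 5 kb windows. No 10 kb window was at 0, so the choice does not touch values in 10 kb windows.

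The comparisons, the main window, the distance classes, the gene lists and 14 of the 18 alternatives were fixed before the data were examined. The treatment of windows at 0, the local spread used as a yardstick and the other 4 alternatives (log2 without the constant, leaving out positions near the stretch at 0, 5 kb windows with zeros kept, and pairing with the cortical position on the other side, 635 bases away) were chosen after the values had been seen. Windows of 10 kb were the main scale. The viewpoint was placed at the midpoint of each file, 86814834 in the cortical and 86814199 in the hippocampus file, 635 bases apart. The midpoint is an inference from the shape of the files. Mean signal was computed in classes of 0 to 10, 10 to 25, 25 to 50, 50 to 100, 100 to 200, 200 to 500 and 500 to 1000 kb on the side of lower and of higher coordinates. Sides are named by coordinate, because the strand of the gene was not taken from a reference of this build. Ratios and excesses were taken on log2 of the signal plus the constant of the file, except class ratios, which compare mean signals. Local maxima were peaks of the excess over an isotonic decay with distance fitted to each side, at least 10 kb from the midpoint and 10 kb apart, up to 5 per side. For comparison, each hippocampus position was paired with the cortical position 365 bases away, and distances in the shared region count from the midpoint of the hippocampus file. The centred difference is the log2 difference minus its median over 172 shared positions beyond 10 kb. As a yardstick in place of replicates, the local spread is the SD of differences between 10 kb windows that adjoin, divided by the square root of 2. It was 0.32 on the log2 scale in the cortical and 0.46 in the hippocampus file, and 0.56 for both combined. It contains real variation along the chromosome and is not an error between animals or cultures. It describes single windows, and means over many windows vary less, so class contrasts of the cortical library were also taken around 140 other centres (the far class of 500 to 1000 kb both around each centre and around the midpoint), every 10 kb from 200 to 890 kb on each side. These centres overlap and describe that library alone, and they were added after the values had been seen. Highest, lowest and most different positions were listed at least 10 kb apart (2 kb for 2 kb windows). Circular shifts of the hippocampus profile describe how often these 2 profiles would match by position alone. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

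The functions were tested on simulated data: with contacts of 10 kb planted at 1 log2 unit in 100 simulated profiles of 191 positions, 95.2% were found for the cortical and 93.8% for the hippocampus settings, and at 2 log2 units 99.5% and 99.7%, assuming 5 values per kb. No profile without planted contacts was simulated, so the share that maxima would match by position alone is unknown. Both planted sizes were above every excess listed in the results, so these shares do not apply to the maxima described there. Alternatives changed the window scale (5, 20 and 40 kb), the stretch left out around the midpoint, the decay model, the number and tolerance of maxima and the centring. Contact at named genes was planned but not computed, because the gene table used here is of assembly GRCm38.p6 and coordinates were not carried between builds. From that table only names, the chromosome and the order of genes were taken. The rule for named genes was every gene of the fixed lists inside the region both tables cover, and other protein-coding genes starting within 10 kb of a listed maximum or of a region of largest difference. Its position criteria could not be applied, so the 18 genes of the lists, all found in the table, are named by order alone. The 2 long non-coding RNA genes next to Fos lie outside the rule and were added after the gene order was seen. Restricting the similarity to 100 kb was planned too, and leaves the shared positions as they are.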

Results

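Contacts of the Fos promoter were measured by 4C-seq in 1 library of cultured mouse cortical neurons and 1 library of mouse hippocampal tissue, to ask which surrounding regions, among them putative enhancers, it touches. Signal was listed up to 1000 kb to each side of the midpoint in the cortical neurons and up to 100 kb in the hippocampus. Signal is given relative to the highest 2 kb window of the same library. The bounds in parentheses are the authors' spread of values within a window, not a replicate error, and read depth is unknown.

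All coordinates are mm9, on chromosome 12, where Fos lies. In gene order, the nearest protein-coding gene at lower coordinates was Tmed10, a cargo receptor of the early secretory pathway, followed by Nek9, a mitotic kinase, Zc2hc1c, Acyp1, an acylphosphatase, Mlh3, a mismatch repair protein, and Eif2b2, a subunit of the translation factor eIF2B. Pgf, a growth factor of the VEGF family, Rps6kl1 and Dlst, a subunit of the 2-oxoglutarate dehydrogenase complex, came next. At higher coordinates the first 2 protein-coding genes were Jdp2 and Batf, which like Fos encode basic leucine zipper transcription factors, so that the 3 genes of the AP-1 list were consecutive among protein-coding genes. Flvcr2, a membrane transporter, came next, and Ttll5, a tubulin-modifying enzyme, after it, with 1 protein-coding gene outside the lists between them. Tgfb3, a TGF-beta ligand, Ift43, a ciliary transport protein, Gpatch2l and Esrrb, an orphan nuclear receptor, followed in that order. The long non-coding RNA genes Gm38543 and Gm32296 were the immediate neighbours of Fos on the lower and higher side. Their mm9 positions were not used here, so the contact regions described next carry coordinates and no gene assignment.

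The first comparison asked how contact changed with distance. In the cortical neurons signal between 10 and 50 kb was above that at larger distances by a small factor, and it did not fall steadily. Within 10 kb the mean 10 kb signal was 0.120 ± 0.0427 (SD over 18 overlapping windows), lower than at 10 to 25 kb. At 10 to 25 kb it was 0.155 ± 0.0399 (30 windows), at 25 to 50 kb it was 0.137 ± 0.0402 (50 windows), at 50 to 100 kb 0.117 ± 0.0248 (100 windows), at 100 to 200 kb 0.125 ± 0.0316 (200 windows), at 200 to 500 kb 0.116 ± 0.0242 (600 windows), and at 500 to 1000 kb 0.113 ± 0.0261 (992 windows). The mean over 10 to 50 kb was 1.28-fold that at 500 to 1000 kb, a log2 difference of 0.35. Taken around 140 other centres of the cortical table, 200 to 890 kb from the midpoint, this contrast reached 0.21 at most (SD 0.13), and 0.30 at most with the far class kept at 500 to 1000 kb from the midpoint. The lowest values were -0.42 and -0.27, in the same order. In the hippocampus the mean within 10 kb was 0.264 ± 0.0863 (18 windows), also below that at 10 to 25 kb. Further out the means were 0.284 ± 0.0913 (30 windows), 0.273 ± 0.0894 (50 windows) and 0.238 ± 0.0575 (92 windows) at 10 to 25, 25 to 50 and 50 to 100 kb. There the log2 difference between 10 to 50 and 50 to 100 kb was 0.22, and in the cortical library it was 0.30, a value that 1 of the 140 other centres reached. The lowest value among those centres was -0.46. For contrasts with distance only values as high are counted, and for contrasts between the sides those as large in either direction. The hippocampus table is too short for such a reference. Within the cortical library, the 2 highest 10 kb windows of the whole 2001 positions lay near Fos, from 86797835 to 86807834 (signal 0.235, bounds 0.0165 to 2.61) and from 86835835 to 86845834 (0.233, bounds 0.0340 to 1.43). None of the 10 kb windows beyond 200 kb reached either level. The first of the 2 holds the highest 2 kb window of the library at its lower end. The 10 kb window centred 1 kb above it had a signal of 0.184, below the 0.213 at -366 kb.

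**Figure D1:**
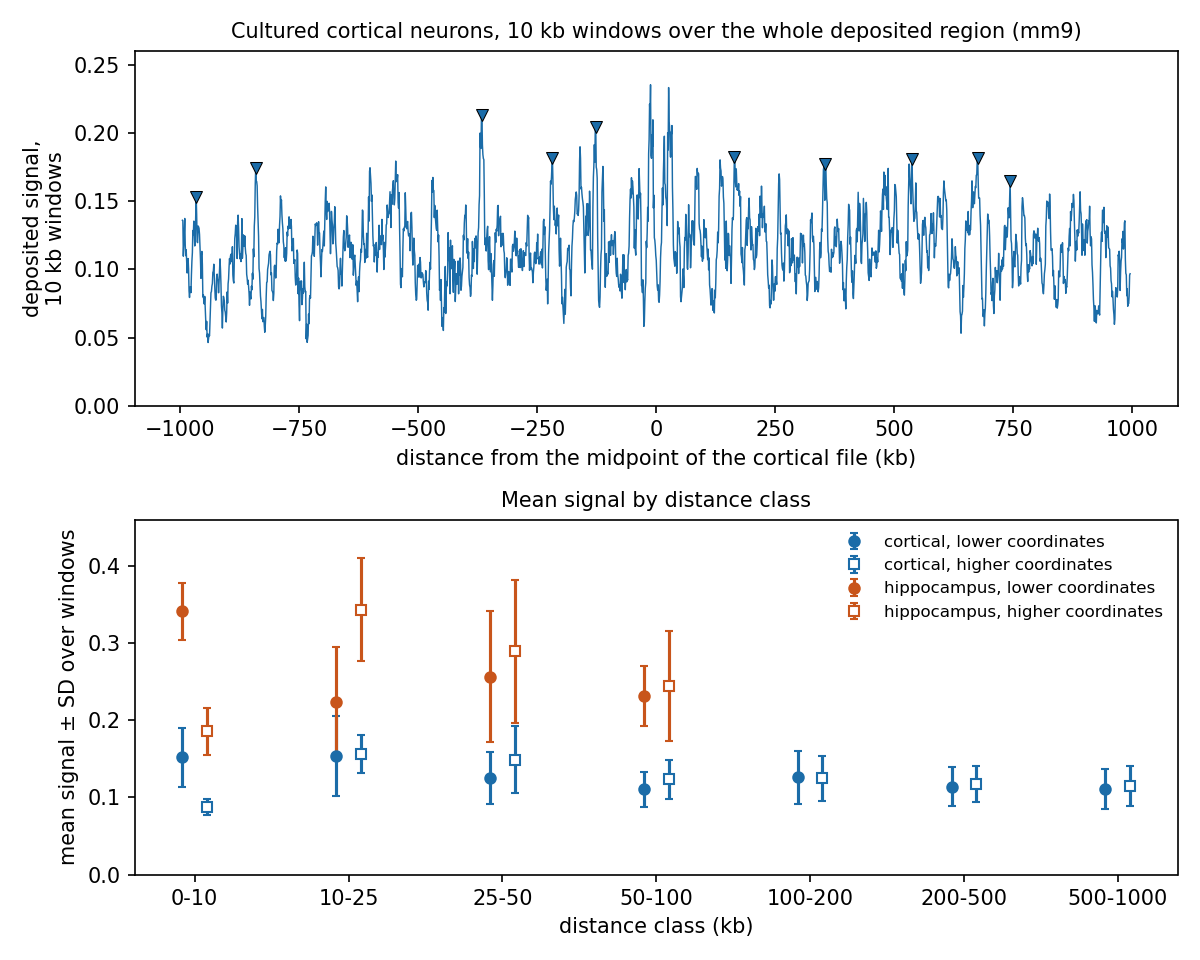
The upper panel plots the cortical signal in 10 kb windows against distance from the midpoint in kb, with the 10 local maxima of the whole file as triangles, and the lower panel plots the mean signal by distance class and side, with bars for the SD over windows. The cortical class means lie between 0.0880 and 0.156, and the hippocampus means between 0.186 and 0.344.

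The second comparison set the side of lower coordinates against the side of higher coordinates. Next to the viewpoint both libraries had more signal on the lower side. Within 10 kb the cortical mean was 0.152 ± 0.0382 on the lower and 0.0880 ± 0.0103 on the higher side (9 windows each), and the hippocampus mean was 0.341 ± 0.0365 against 0.186 ± 0.0307. These ratios of 1.73 and 1.84, or 0.79 and 0.88 on the log2 scale, exceeded the local spreads. Of the 140 other centres in the cortical table, 2 had a ratio within 10 kb as far from even as the cortical one. In 20 kb windows the log2 values fell to 0.40 and 0.28, and in 40 kb windows they turned to -0.13 and -0.25. Windows of these sizes near the midpoint reach across it. The 10 kb windows centred nearest to the midpoint do so too, and those at the outer end of the class reach beyond 10 kb. From 10 to 25 kb the hippocampus had 1.53-fold more signal on the higher side (0.344 ± 0.0669 against 0.224 ± 0.0716, 15 windows each), a log2 difference of -0.62 for lower over higher. The cortical library had 0.156 ± 0.0250 on the higher and 0.154 ± 0.0516 on the lower side, a difference of -0.02. The same difference ran from -0.80 to 0.82 (SD 0.34) around the 140 other centres, which describe the cortical library alone. That range includes the hippocampus value of -0.62. From 25 to 50 kb the log2 differences were -0.25 and -0.17, and from 50 to 100 kb -0.16 and -0.08, in cortical neurons and hippocampus respectively. Around the other centres 45 and 65 of 140 had a difference as large as the cortical one in these 2 classes. Whether the asymmetry at 10 to 25 kb differed between the tissues was not tested, since each had 1 library.

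The third comparison concerned local contact maxima in the region both tables cover. Both libraries had a peak at about +26 kb, one at -35 kb, one at -86 kb, one at +69 kb and one near +85 kb from the midpoint. The +26 kb peak was the highest 10 kb window of the hippocampus, from 86835200 to 86845199 (signal 0.486, bounds 0.0665 to 3.34), and the corresponding cortical peak was the second highest of that library, from 86835835 to 86845834. Their excess over the decay was 0.43 log2 in the hippocampus and 0.46 in the cortical neurons. At -35 kb the peaks were from 86774200 to 86784199 in the hippocampus (0.374, excess 0.71) and from 86773835 to 86783834 in the cortical neurons (0.174, excess 0.49). Near +85 kb the hippocampus peak was from 86892200 to 86902199 (0.391, excess 0.75) and the cortical peak from 86895835 to 86905834 (0.174, excess 0.51). The peaks at -86 kb had an excess of 0.42 and 0.32 and those at +69 kb an excess of 0.35 and 0.28, in the same order. A further pair, at -51 kb in the cortical neurons and -47 kb in the hippocampus, had an excess of 0.43 and 0.49. The peaks at -35 kb, near +85 kb and in this pair exceeded the local spread of their library in both. The +26 kb peak did so in the cortical neurons and was at 0.939 of it in the hippocampus, and those at -86 and +69 kb were below it in both. Maxima are chosen for their height, so passing that spread is a weak mark. Values within a window varied far more than any of these excesses, with a median spread of 2.18 log2 in the cortical and 2.92 in the hippocampus library. Among cortical 10 kb windows beyond 200 kb, 1.44% were at least as high as the cortical peak at -35 kb, 9.23% as high as that at +69 kb and 28.8% as high as that at -86 kb. Which maximum ranked first on a side depended on the window and the decay: with a straight-line decay the first on the higher side was at +27 kb in the cortical and +26 kb in the hippocampus library. On the lower side it was at -11 kb, the highest cortical 10 kb window, and at -35 kb. The isotonic decay cannot rise with distance and takes up high values at its inner edge. With it, maxima at -11 kb (cortical) and -13 kb (hippocampus) had an excess of 0.14 and 0.07. Other pairs below the local spread were at +46 and +42 kb (0.16 and 0.13) and at -69 and -63 kb (0.13 and 0.12), in the same order. At the hippocampus positions of these pairs, +42 and -63 kb, the cortical excess was -0.15 and -0.08. At the cortical positions, +46 and -69 kb, the hippocampus excess was 0.05 and 0.07. The cortical window at -69 kb contains a whole stretch of 7 kb listed at 0 in every 2 kb window of both libraries.

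Low points were shared as well. Taking windows at least 10 kb apart, the lowest 10 kb windows of the region both tables cover were centred at 86788834 in the cortical neurons (signal 0.0582) and 86788199 in the hippocampus (0.0792), about 26 kb from Fos on the lower side. The next lowest were at 86820834 (0.0758) and 86866834 (0.0763) in the cortical library, and at 86866199 (0.108) and 86820199 (0.153) in the hippocampus. A stretch of 7 kb, from 86742200 to 86749199, listed at 0 in every 2 kb window of both libraries, is not counted among the low points, because part of such runs behaved as windows without values. The 10 kb signal in its middle was 0.0909 in the cortical neurons and 0.156 in the hippocampus.

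Beyond the shared region, the maxima of the cortical library had an excess over the decay of 0.56 to 0.86 log2. Here the decay was fitted to the whole table, and for the maxima near Fos to the shared region alone. The maxima were also picked from more windows, so the 2 sets of excesses cannot be compared. Their signals, 0.213 at most, were below those of the 2 highest windows near Fos (0.235 and 0.233). In the whole table the largest excess on the lower side was at -366 kb, from 86443835 to 86453834 (signal 0.213, bounds 0.0367 to 1.12, excess 0.86), followed by -841 kb (0.174, excess 0.76) and -127 kb (0.204, excess 0.73). On the higher side the largest were at +675 kb, from 87484835 to 87494834 (0.181, excess 0.63), and +537 kb (0.181, excess 0.60). The hippocampus table does not extend to these positions, so they were compared with nothing.

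The fourth comparison asked how alike the profiles of cultured neurons and adult hippocampal tissue were. Across the 172 shared positions the signals rose and fell together, with a Spearman correlation of 0.854 and a Pearson correlation of 0.842 on the log2 scale. After removal of the distance decay the values were 0.814 and 0.865. Positions 1 kb apart share most of their window and are not replicates, so no p-value was computed. In windows that did not overlap (18 positions) the Spearman correlation was 0.816 for the signals and 0.750 for the excess over the decay. No shifts were run on those 18 positions. Over 171 circular shifts of the hippocampus profile the median correlation of the excess was 0.0278, 95% of the shifts lay between -0.457 and 0.525, and no shift reached the observed value. Coincidence of the peaks alone was a weaker measure. All 10 hippocampus maxima lay within 10 kb of a cortical maximum, but 73 of the 171 shifts gave as high a share. Within 5 kb, 8 of 10 matched, which 13 of 171 shifts equalled.

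**Figure D2:**
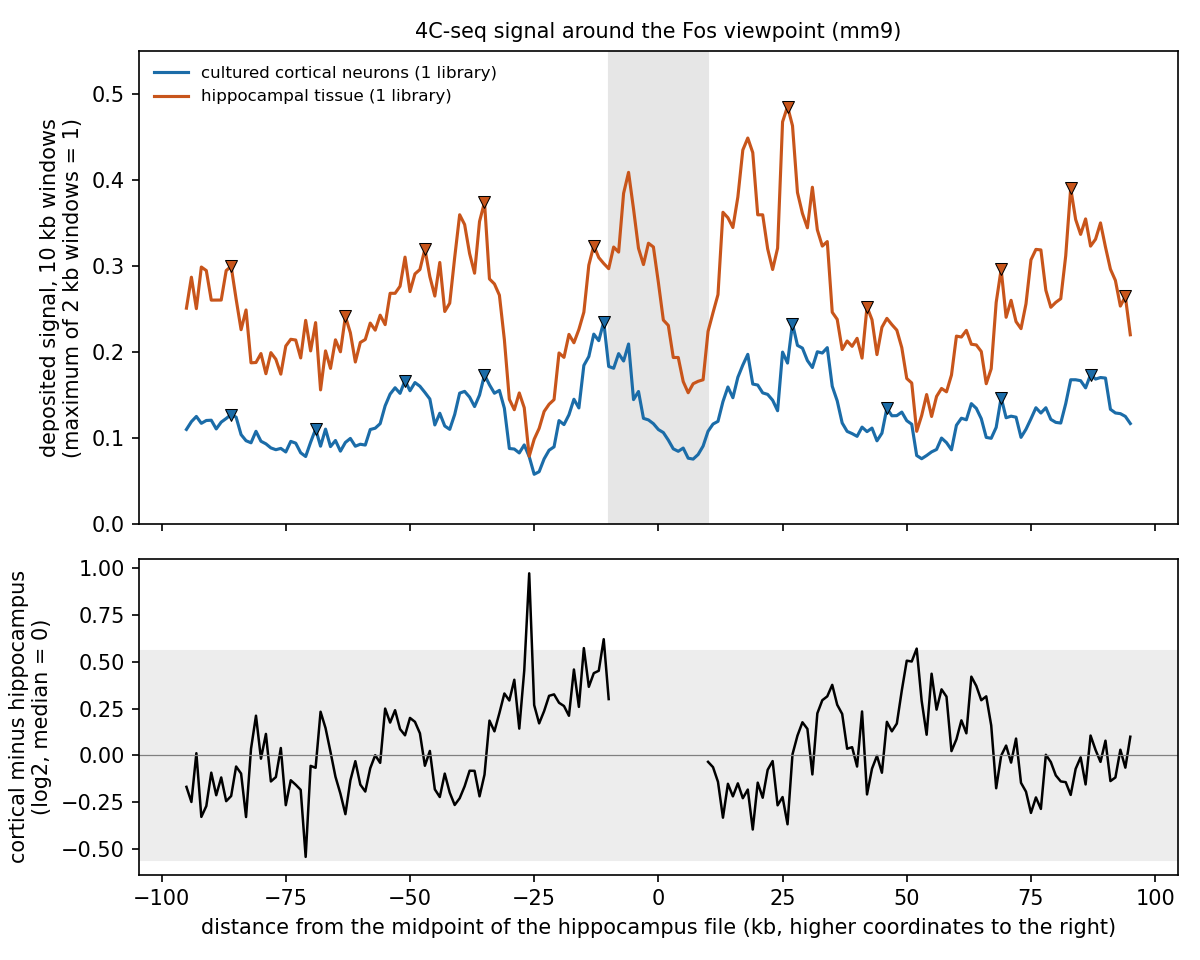
The upper panel plots the signal in 10 kb windows of both libraries against distance in kb from the midpoint of the hippocampus file, with triangles at the local maxima and grey over the 10 kb left out on each side, and the lower panel plots the centred log2 difference, with grey over the combined local spread of 0.56. Both profiles peak at about +26 kb and dip at about -26 kb, and 4 of 172 positions leave the grey band.

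The last comparison was the difference between the libraries. As deposited, the hippocampus was higher at all 172 positions, by a median of 1.97-fold (log2 difference -0.98 for cortical minus hippocampus). This level depends on the scaling of each library to its own maximum. After centring, the SD of the difference was 0.24 on the log2 scale, and 4 positions, or 2.33%, differed by more than the combined local spread of 0.56. That spread combines the 2 libraries as if they varied independently, although their log2 signals had a Pearson correlation of 0.842. Variation along the chromosome that both share cancels in the difference, so this yardstick is wide. A difference below it is therefore not shown to be absent. With this centring the 4 positions past it were relatively higher in the cortical neurons. Other scalings changed that: against the same spread (0.560 to 3 digits), the difference at -71 kb was -0.564 with equal sums and -0.72 after quantile normalization, which also lowered that at -26 kb to 0.51. Among positions at least 10 kb apart, the largest difference was 0.97 at -26 kb, in the trough of the hippocampus (0.0787 in the cortical neurons at 86787834 and 0.0792 in the hippocampus at 86788199), where the signal changed steeply with position. Paired with the next cortical position (0.0582 at 86788834, 635 bases away), the difference there was 0.57, and 5 positions between -26 and -12 kb passed the spread, the largest 0.72 at -21 kb. In 5 kb windows the difference at -26 kb was -0.07 and the largest was 1.07 at -29 kb, and in 20 kb windows these were 0.28 and 0.55 at -21 kb. Next came 0.62 at -11 kb, where the cortical library had its highest 10 kb window (0.235 against 0.303), and 0.57 at +52 kb (0.080 against 0.108). With the other pairing these were 0.27 and 0.50, below the spread. The fourth position past the spread, at -15 kb, lies beside the one at -11 kb. The largest differences in the other direction were -0.54 at -71 kb (-0.29 with the other pairing), -0.40 at +19 kb (0.163 against 0.432) and -0.33 at -83 kb, all below the combined spread. Most of the 10 kb window at -71 kb lies inside the stretch at 0, so its difference may rest on the part outside that stretch. In 20 kb windows the difference at -71 kb was 0.05. Without the stretch the largest difference in this direction lay at +19 kb. At +26 kb, on the shared peak, the difference was -0.37, but -0.06 with the other pairing, which meets the cortical peak. At the 6 positions at least 10 kb apart the bounds of the 2 libraries overlapped. The largest difference as deposited among them was -1.52, against median spreads within windows of 2.18 and 2.92 log2. The overlap therefore does not tell whether the libraries differed.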

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

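The test of an explanation in this part was chosen after the result was seen. The change of signal with distance on the lower side had opposite signs in the 2 libraries: from 50 to 100 kb towards 10 to 25 kb the log2 difference was 0.477 in the cortical neurons and -0.051, close to level, in the hippocampus. In 5, 20 and 40 kb windows it was 0.56, 0.40 and 0.21 in the cortical neurons and -0.17, -0.02 and -0.01 in the hippocampus. No spread was computed for the hippocampus mean. The difference between the tissues was not tested, because each had 1 library. A single strong cortical window, the highest 2 kb window at -16 kb, stays open as a cause. It is not shown to be particular to the cortical library. The hippocampus 2 kb signal was 0.832 at the position 635 bases below it and 0.226 at that 365 bases above. Without the 10 kb windows that touch this 2 kb window, the cortical contrast was -0.02984, but 4 of 15 windows were left, and the hippocampus contrast, with 3 of 15 windows left, fell to -0.87 as well. Leaving those windows out thus keeps a stretch that is low in both libraries and does not isolate the strong window. The difference between cultured embryonic cortical cells and adult hippocampal tissue, in region, age and cell mixture, stays open too and was not tested.

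At -26 kb, the position of largest difference, the centred differences in 4 kb windows 3 kb below, at and 3 kb above it were 1.67, 0.31 and 0.86, against a combined local spread of 0.84 at that scale.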

How the results depend on the processing

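No paired analysis was possible because each group holds 1 library. Across 33 results and 18 alternatives, 194 of 229 recomputed values moved by less than a set limit, 29 moved by more, and 6 that were past the limit changed sign. The limit was the local spread (log2 values), 0.1 (correlations), 10 kb (positions) or 1.5-fold (counts), and it is wide for class means. Some values could not move by construction, such as correlations of the signals under another decay and positions of the largest differences without centring. The share that stayed within the limit is therefore no measure of robustness. In all, 9 log2 values changed sign, among them the hippocampus ratio of lower over higher at 50 to 100 kb, which became 0.04174 in 5 kb and 0.07706 in 40 kb windows. The correlations ranged from 0.7503 to 0.8839 over all settings run. Contact at neighbouring genes and its alternatives were not run. The settings with zeros kept, without the constant, without the region at 0 and with the other pairing were chosen after seeing the data.

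The position of the largest difference in favour of the cortical library depended on the window and the pairing. At -26 kb the difference was -0.06932 in 5 kb windows, -0.07629 with zeros kept, 0.2806 in 20 kb and 0.1526 in 40 kb windows, 0.5685 with the other pairing and -0.005759 without centring. The largest was 1.066 in 5 kb windows and 1.059 with zeros kept, both at -29 kb, and 0.5511 in 20 kb windows and 0.7218 with the other pairing, both at -21 kb. It lay at 51 kb (0.2216) in 40 kb windows and at -11 kb after quantile normalization. Without centring its size was -0.005759. At -71 kb the difference was 0.04964 in 20 kb windows and -1.521 without centring. The largest difference in favour of the hippocampus lay at -98 kb (-1.245) in 5 kb windows, was -4.353 with zeros kept and -1.521 without centring, and lay at 19 kb without the region at 0 and 18 kb with the other pairing. Leaving out centring shifts all differences by the median, by construction, and the cause of the other changes was not tested.

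The cortical maximum with the largest excess on the higher side moved to 30 kb in 5 kb windows, with or without zeros kept, to 22 kb in 20 kb and 32 kb in 40 kb windows, and to 27 kb with a straight-line decay or 5 kb left out. On the lower side it moved to -51 kb in 5 kb and -21 kb in 40 kb windows, -11 kb with the straight line and -71 kb with zeros kept. In the hippocampus it moved to 26 kb with the straight line, -54 kb in 40 kb windows and -71 kb with zeros kept. With 3 maxima per side, 6 of 6 were shared, a share that 23 of 171 circular shifts also reached. In 20 kb windows the excess of the lower side within 10 kb was 0.4039 in the cortical and 0.2832 in the hippocampus library. In 40 kb windows, which cover both sides near the midpoint, it became -0.1265 and -0.2501.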

Other observations

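The tests of explanations in this part were chosen after the results were seen, while the correlation without the decay and its 20 kb setting were planned. The highest 2 kb window of the cortical library, at -16 kb (centred at 86798834), stood at 1 with bounds of 0.0465 and 19.4. The next highest windows at least 2 kb apart reached 0.577 at -366 kb and 0.530 at +28 kb. How wide the feature at -16 kb is was not measured. The hippocampus positions on either side had 0.832 (635 bases below) and 0.226 (365 bases above). The 3 highest hippocampus windows at least 2 kb apart differed less in signal, 1 at +14 kb, 0.946 at +30 kb and 0.866 at -32 kb. Because each library is scaled to its highest 2 kb window, the cortical levels rest on the window at -16 kb. Expressed in units of the constant added in each file, these maxima were 176 in the cortical and 179 in the hippocampus library.

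The cortical signal changed by a small factor with distance. The upper bound changed more than the centre: its median fell from 0.798 at 10 to 50 kb to 0.487 at 500 to 1000 kb, a log2 change of 0.70 against 0.33 for the central value, while the lower bound changed by -0.12. A candidate explanation is that averaging logs hid a decay carried by few strong values. The spread within windows was larger near Fos by 0.352 log2 (2.45 against 2.10), but stretches of 40 kb beyond 200 kb reached 0.52, so the test did not decide. A viewpoint away from the midpoint of the file stays open too, although the midpoints of the 2 tables lie 635 bases apart. Only a viewpoint over 49 kb away was tested, and the test did not decide. The highest 49 kb window lay 7 kb from the midpoint in both libraries, but in the cortical one it exceeded the highest window elsewhere, at -150 kb, by 0.01085 log2 against a local spread of 0.14 for such windows. Background ligation that is the same at all distances was not tested and stays open.

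The 2 profiles rose and fell at the same positions. A common decay with distance is argued against by the correlation of 0.814 that was left after the decay was removed, above all 171 circular shifts (highest 0.787). In 20 kb windows 1 of 161 shifts, and with the other pairing 1 of 171, reached the observed value, in both settings a shift by 1 position. The stretch at 0 in both libraries is argued against as the whole cause, because the correlation was 0.816 without positions within 10 kb of it. What stays open is that both libraries were cut with the same enzymes and mapped to the same genome, so that fragment length, GC content and unique mapping could shape both alike: 87.5% of the 2 kb windows at 0 in the hippocampus (7 of 8) were also at 0 in the cortical library, where 11 were at 0 in that region, and 6 of the 7 shared ones form 1 run, and no genome of this build was used to test the fragments. Contacts of Fos that cortical and hippocampal cells share stay open as well, as a hypothesis.

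Widening a window by 1 kb left the signal the same, to within 1e-12, in 0.639% of steps in the cortical file and 2.38% in the hippocampus file. In the region of the hippocampus file the cortical share was 2.60%. In random sequence, 78.3% of 1 kb stretches would lack a site of a 6-base cutter, 37.7% a 6-base site with 2 degenerate bases, as HindII has, and 2.01% a site of a 4-base cutter such as DpnII. The observed shares were nearest to the last, although the labels name HindII for the first digestion, and what the tables count as a fragment end is not given in the sources used here.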
